A study of Vitis amurensis with 6 samples.

How the data were processed

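RNA was extracted from callus, a mass of unorganised plant cells grown in culture, of Vitis amurensis (the Amur grape), and sequenced on 6 libraries. Per the labels' protocols, petiole segments were transformed, the transgenic callus was selected with kanamycin and kept on solid B5 medium in the dark at 25 °C, and 15 days after transfer to new medium it was held at 4 °C for 24 hours. The labels put 3 libraries in a group called EV, whose genotype label reads Envelope, and 3 in a group that overexpresses VaWRKY12, a member of the WRKY family of plant transcription factors. All 6 libraries were cold-treated, so the design holds 1 comparison, between genotypes. The labels do not say whether the libraries of a group came from separate cultures or callus lines, so p-values measure the spread between these samples, which may be technical.

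Trimmomatic, HISAT2 2.0.5 and edgeR are named in the submitters' processing notes, without their roles. The read counter, genome build, annotation and count filter are not given in the sources used here. Per the file headers and values, the deposited table holds reads for 16645 genes in each library, taken here as an estimated count (expected count). The columns are headed Reads, and the headers do not say that the values were estimated. These counts were not normalised, and 16.6% to 21.0% of the genes in a library had a count that was not a whole number (tolerance 1e-06). In all, 6623 genes (39.8%) had such a count in any library. How fractions of a read arose is not given in the sources used here, and genes with them may share reads with other gene models. The deposited RPKM values were recomputed from the reads, the coding length and the column totals with a largest difference of 4.7e-06, and were not tested. The authors' deposited table also gives a log2 fold change and mean log2 CPM, an F score, and a p-value with its false discovery rate for each gene. The lengths in the table are sums of exons and multiples of 3 for 100% of the genes, and are called coding length here. All genes in the table had at least 1 CPM in at least 2 libraries, as tested on the values, so genes below that level were not analysed here. Strand use in counting is not given in the sources used here, so overlapping antisense genes cannot be told apart.

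The reads were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at a minimum count of 10, which kept 16317 genes and left out 328. Libraries were scaled by TMM (factors 0.979 to 1.03). The main test was the two-sided quasi-likelihood F test (glmQLFit and glmQLFTest) of VaWRKY12 against EV with no covariate, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was derived from the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Library totals ran from 8795632 to 14966502 reads, so that 3 reads, the floor used for a count of 0, stand for 0.2 to 0.341 CPM. Counting intervals (exact binomial, 95%) and floors cover counting error only.

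The test was checked on simulated data for this comparison. Counts for the 16317 genes were drawn 10 times from the real means, library sizes and dispersions, each time with 200 genes changed. On average 69.9% of the genes changed by 1 on the log2 scale and 96.4% of those changed by 2 were called, 0 in the wrong direction. Of all calls, 8.43% fell on genes that had not been changed, above the nominal 5%. In a further set, a chromosome 2 shift of -0.15 put into 1 library was measured as -0.127, with the other chromosome medians within 0.0302 of 0. With the real calls placed at random along the genome the neighbour count was 0.908 times its permuted mean (permutation p = 0.846), and with 40 neighbouring pairs put in it was 1.21 times (permutation p = 0.0149).

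The comparison, its test, the alternatives, 36 gene lists to be matched by gene descriptions, and the rule for named genes were fixed before the data were examined. The file gives gene identifiers with no names or descriptions, and no table pairing them was used here, so 0 of the 36 lists matched a gene, the gene list tests were not run, and the row of WRKY12 was not identified. The level of the overexpressed gene therefore could not serve as a check of the labels. The rule named genes annotated as WRKY12, the largest rises and falls among called and described genes with a mean of at least 50 reads in the higher group and no overlap between groups, called members of the lists, and the most abundant called gene in each direction. With no descriptions, that condition was dropped after the file was seen, and 1 gene with the largest change and 1 most abundant gene are named in each direction. Coordinates are printed as the file gives them.

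Comparisons by expression level, coding length, exon number, chromosome and gene order were chosen after the file was seen. The most abundant genes were compared with the rest by Fisher's exact test (two-sided). Length and exon classes were compared with the Mantel-Haenszel test over 10 classes of expression level and adjusted over 6 tests. The shares of risen and fallen genes on 21 classes of sequence (19 chromosomes and the unplaced sequences) were compared by Fisher's exact test and adjusted over 42 tests. Counts on the 19 chromosomes were also compared with all 16317 circular shifts of the calls along the gene order (one-sided, adjusted over 38 tests), since neighbouring calls are not independent. In simulated data this test gave p = 0.124 for chromosome 19 with calls placed at random by permutation. It gave 0.0213 with 70 fallen genes put in as well, at the first genes of chromosome 19 that were not called. Gene order was compared with 10000 permutations of the calls within each chromosome (one-sided). Neighbours are tested genes that follow each other by start position, so genes that were not tested are skipped. Chromosome medians were compared between groups with an exact permutation test, whose smallest p with 3 against 3 is 0.1. Alternatives were other size factors, library totals alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), other count filters, a replicate block, each library left out in turn, and a fold threshold. Added after the data were seen were the newer quasi-likelihood method, reads with their fractions, genes with whole reads only, and cyclic loess scaling. Figures were drawn with matplotlib 3.10.9.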

Results

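Gene expression was measured by RNA sequencing in cold-treated callus of Vitis amurensis, in 3 EV libraries and 3 libraries of callus overexpressing VaWRKY12. The series set out to find how VaWRKY12 overexpression changes expression in the cold and which genes lie downstream of it. EV replicates 1, 2 and 3 held 10290034, 10647037 and 8795632 reads on the genes of the table, and VaWRKY12 replicates 1, 2 and 3 held 14966502, 9321930 and 9139429. The 10 most abundant genes took 1.97% to 2.56% of the reads of a library. Across genes, log2 CPM values correlated at 0.980 to 0.986 within EV, 0.973 to 0.987 within VaWRKY12 and 0.927 to 0.969 between the groups. The first principal component held 60.5% of the variance and separated the groups. The second held 18.4% and set VaWRKY12 replicate 3 (32.5) apart from VaWRKY12 replicates 1 and 2 (-25.2 and -20.0). VaWRKY12 replicate 3 correlated with them at 0.973 and 0.974, against 0.987 between those libraries. The biological coefficient of variation was 0.126 among EV libraries and 0.170 among VaWRKY12 libraries (n = 3 each). No pair of replicate libraries agreed within sampling noise (chi-square per degree of freedom 6.41 to 23.1), so none was treated as 1 library deposited more than once.

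In VaWRKY12 callus 940 genes were higher and 1005 were lower than in EV callus after cold, 11.9% of the 16317 genes tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). The median log2 fold change was 0.99 among risen genes, -0.87 among fallen genes and 0.01 among all tested genes. Of the risen genes, 460 changed by at least 1 on the log2 scale and 161 by at least 2. Of the fallen genes, 419 and 152 did so. For 32.1% of all tested genes the 3 libraries of one group all lay on one side of the other group, which chance gives for 10% of genes. Among the risen genes, 12 had at most 3 reads in each EV library and a mean of 20 or more in VaWRKY12, and 7 fallen genes showed the opposite. The number of higher genes was 457 without EV replicate 1, 469 without EV replicate 2, 549 without EV replicate 3 and 577 without VaWRKY12 replicate 2. The number of lower genes was 588 without EV replicate 1, 524 without EV replicate 2, 663 without VaWRKY12 replicate 1 and 642 without VaWRKY12 replicate 2.

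**Figure D1:**
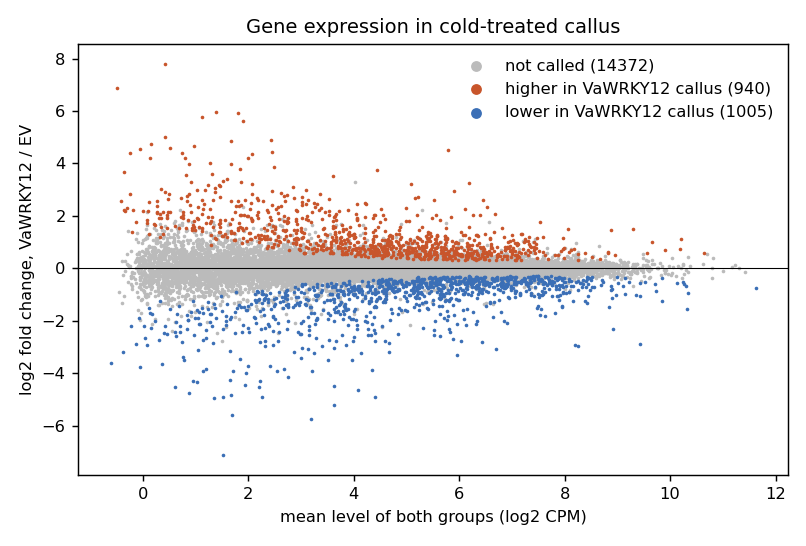
Log2 fold change of VaWRKY12 over EV callus (vertical) against the mean level of both groups in log2 CPM (horizontal), with 1 point per tested gene. Orange points are the 940 genes called higher, blue points the 1005 called lower and grey points the 14372 not called.

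The files pair the gene identifiers with no names, so genes are given by identifier and position. Among called genes with a mean of at least 50 reads in the higher group and no overlap between groups, the largest rise was in GSVIVT01035801001, a gene of 12 exons on the minus strand of chromosome 4 from 4478872 to 4485156. It had 0, 1 and 2 reads in the EV libraries and 90, 41 and 95 in the VaWRKY12 libraries. Its mean rose from 0.108 ± 0.115 CPM to 6.93 ± 3.28 CPM (SD, n = 3), and the summed reads scaled to library totals were 67-fold higher (95% counting interval 22.6 to 327, edgeR adjusted p = 0.00248). This ratio rests on 3 EV reads and was 43.8 (14.8 to 214) without EV replicate 1 and 142 (25.1 to 5620) without EV replicate 3. The largest fall under the same limits was in GSVIVT01021182001, a gene of 5 exons on the minus strand of chromosome 10 from 2337706 to 2342096. It had 45, 93 and 35 reads in EV and 0, 1 and 0 in VaWRKY12. Its mean fell from 5.74 ± 2.63 CPM to 0.0353 ± 0.0612 CPM (SD, n = 3), with summed reads scaled to library totals 195-fold lower (95% counting interval 34.5 to 7730, edgeR adjusted p = 0.00216). The latter ratio rests on 1 read in VaWRKY12 replicate 2. Without that library it was at least 46.8-fold lower, against a floor of 3 reads over the group, and without VaWRKY12 replicate 1 it was 107-fold lower (19 to 4270).

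The most abundant fallen gene was GSVIVT01022705001, a gene of 5 exons on the minus strand of chromosome 2 from 15324167 to 15325973. It went from 3987 ± 244 CPM in EV to 2364 ± 109 CPM in VaWRKY12 (SD, n = 3), a log2 fold change of -0.75 (SE 0.113, edgeR adjusted p = 0.00572). The most abundant risen gene was GSVIVT01015895001, a gene of 3 exons on the plus strand of chromosome 3 from 19020610 to 19021323. It went from 1271 ± 118 CPM to 1911 ± 112 CPM (SD, n = 3), a log2 fold change of 0.59 (SE 0.114, edgeR adjusted p = 0.0147). Its adjusted p in edgeR was 0.0593 without EV replicate 1, 0.0591 without EV replicate 3 and 0.0560 without VaWRKY12 replicate 2. Both abundant genes had fractions of reads, so part of their counts may be shared with other gene models.

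**Figure D2:**
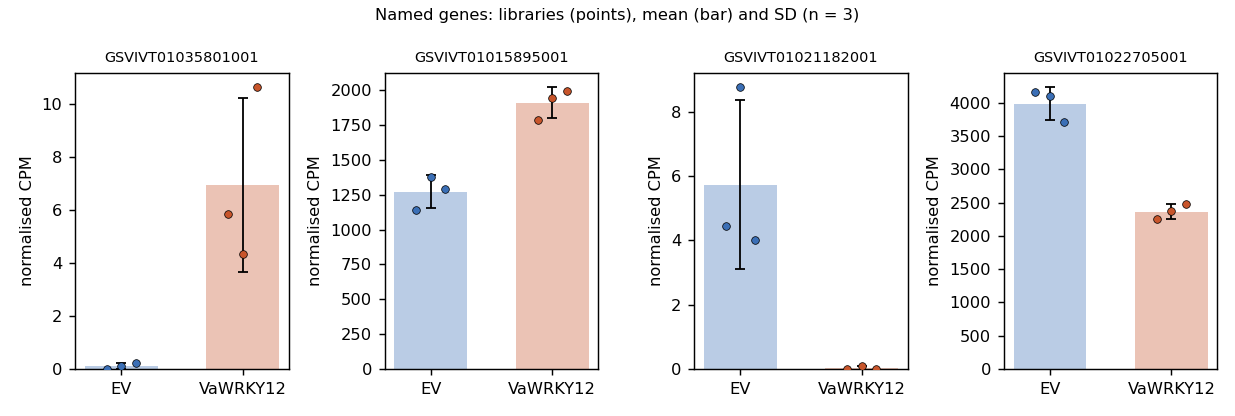
TMM-scaled CPM (vertical, linear, from 0) of the 4 named genes in EV and VaWRKY12 callus. Points are libraries, bars are means and error bars the SD of 3 libraries, and in each gene the 3 libraries of one group lie apart from those of the other.

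Abundant genes fell more often than they rose. Of the 1632 tested genes with the highest mean level (log2 CPM of at least 7.21), 164 fell and 54 rose, against 841 and 886 of the remaining genes. The remaining genes were not evenly balanced, since the balance shifted with level. With genes in 10 classes from low to high level, 67 fell and 102 rose in class 1, and 91 and 111 in class 5. In class 6, 86 fell and 86 rose. In class 8, 112 fell and 91 rose, and in class 9, 113 and 82. Among called genes the odds of having fallen were 3.2 times higher in the most abundant class than in the rest pooled (95% interval 2.3 to 4.5, Fisher's exact test across genes, p = 5.24e-14). The ratio of fallen to risen genes in the class was 3.04, against 1.74 with only whole-read genes and 1.93 (141 fallen, 73 risen) with cyclic loess scaling in limma-voom. The 3295 genes with the shortest coding length rose less often than other genes at matched expression level (Mantel-Haenszel odds ratio 0.553, 95% interval 0.455 to 0.672, adjusted p = 7.98e-09). They also fell less often than the rest (Mantel-Haenszel odds ratio across genes 0.733, 95% interval 0.613 to 0.876, adjusted p = 0.00205). Without matching for level, 159 of the 3255 genes with the longest coding length fell (4.88%), against 4.58% of the shortest and 6.36% to 7.65% of those between. The longest genes were not tested, so whether fewer falls are particular to short genes is not known. The odds ratio of falling for the shortest genes was 0.797 with only whole-read genes, with an unadjusted p of 0.0541. Leaving out VaWRKY12 replicate 3 gave 0.882, with an unadjusted p of 0.159. Genes of 1 exon and genes of more than 10 exons rose and fell at rates that did not differ from those of other genes past the threshold (Mantel-Haenszel test across genes, adjusted p 0.591 to 0.706 for falling and 0.591 to 0.805 for rising). The tests by level, length and exon number treat genes as independent, though neighbouring calls clustered. Their p-values may therefore be too small, and they do not measure the spread between libraries.

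Called genes lay next to called genes of the same direction more often than in permuted gene orders. There were 263 neighbouring pairs of the same direction, against a mean of 117.2 in 10000 permutations (95% range 98 to 138), a ratio of 2.24 with p = 1e-04, the smallest these permutations can give. Pairs of opposite direction numbered 77 against 116.5 (ratio 0.661). Runs of 3 or more neighbours changed alike numbered 49, of which 23 rose and 26 fell, against 6.71 permuted. Without EV replicate 1, 2 or 3 there were 20, 16 and 17 such runs, and without VaWRKY12 replicate 1 or 2 there were 24 and 23. These fits called fewer genes, which lowers the number of runs by itself, so the drop does not show weaker clustering. Their ratios of same-direction pairs to permuted orders were 3.078, 3.063 and 2.513 without EV replicates 1, 2 and 3. They were 2.496 and 3.042 without VaWRKY12 replicates 1 and 2. Without VaWRKY12 replicate 3 there were 45 runs and a ratio of 2.154. With only genes at a mean of at least 50 counts there were 27 runs and a ratio of 1.893. With the model fitted to whole-read genes alone there were 10 runs, and same-direction pairs were 1.60 times as many as in permuted orders (permutation p = 0.000999, the smallest that 1000 permutations can give). Neighbours in that fit skip the genes with fractions of reads, so its counts are not directly comparable with those of all tested genes.

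Runs of 4 or more genes marked 10 regions, 6 risen and 4 fallen, and 35 of their 44 genes had fractions of reads. On chromosome 19, from 2952274 to 2982234, 5 neighbouring genes on the minus strand fell, together from 1400 ± 167 CPM to 689 ± 97.2 CPM (SD, n = 3). On chromosome 2, from 15324167 to 15559736, 6 minus-strand genes that include GSVIVT01022705001 fell from 4880 ± 330 CPM to 2900 ± 147 CPM. Most of both sums was GSVIVT01022705001 alone (3987 and 2364 CPM). On chromosome 15, from 19693653 to 19736451, 4 genes fell from 120 ± 11.2 CPM to 43.5 ± 6.52 CPM. On chromosome 14, from 8127494 to 8294668, 4 genes rose from 2.42 ± 1.44 CPM to 24.6 ± 6.53 CPM, with log2 fold changes of 2.83 to 4.55. These fold changes rest on few EV reads. In EV replicate 1 the 4 genes together held 1.18 CPM, where 3 reads of 1 gene stand for 0.292 CPM. With only genes at a mean of at least 50 counts, 1 called gene of this region remained. On the sequence named 18_random, from 2618234 to 2732180, 5 genes rose from 19 ± 2.98 CPM to 58.5 ± 4.58 CPM. The 5 genes of the chromosome 19 region were called without each library in turn. All 5 had fractions of reads, as had all genes of the region on chromosome 2 and of that on chromosome 14 at 8127494, so none could be tested among whole-read genes. The regions on chromosome 14 at 28307791, chromosome 15 at 15869209, chromosome 16 at 6676172 and chromosome 6 at 4643914 kept only 1 called gene when single EV libraries were left out.

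**Figure D3:**
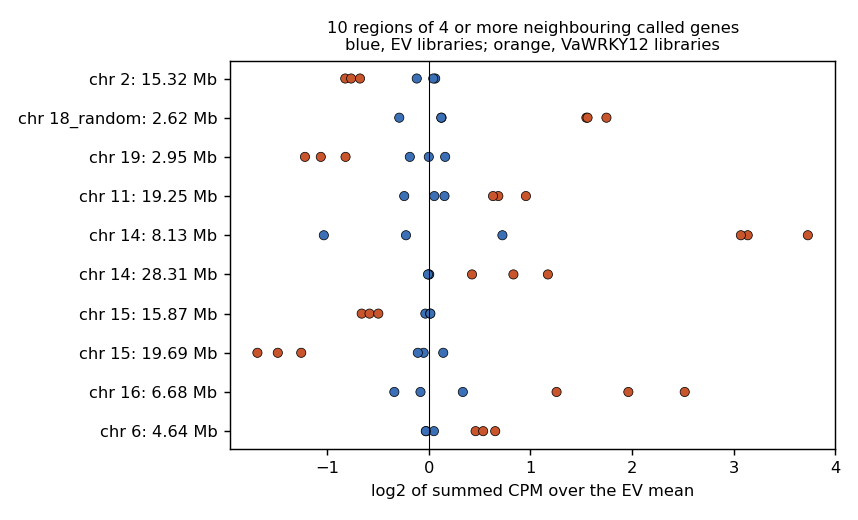
Summed CPM of the genes of each region as log2 of its ratio to the EV mean (horizontal), 1 row per region named by chromosome and start. Blue points are EV and orange points VaWRKY12 libraries, which lie apart in each of the 10 regions. The regions were chosen from genes called in these libraries, so this separation follows from the choice and is no further support.

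On chromosome 19, 70 of 698 genes fell (10%, odds ratio 1.75 against the rest of the genome, 95% interval 1.34 to 2.27, Fisher's exact test, adjusted p = 0.00214 over 42 tests). Fisher's test treats genes as independent, and neighbouring calls clustered. In 16317 circular shifts of the gene order, which keep neighbours together, the mean was 43 fallen genes (permutation p = 0.00184, adjusted p = 0.0699 over 38 tests). The excess did not pass this test. The power of this test for such an excess is not known. In simulated data 70 fallen genes put in on chromosome 19 gave 0.0213 (circular-shift p). Those genes lay in a single stretch at its start, which shifts move as a whole, while the fallen genes here were spread along it. Whether the excess exceeds clustering of neighbours therefore stays undecided. A window from 2599495 to 3512868 held 12 of the chromosome's fallen genes among 50 genes. With only whole-read genes the odds ratio was 1.79 (adjusted p = 0.0546). The median expression of chromosome 19 genes lay at 0.0152, 0.0137 and 0.0305 from the mean of 6 libraries on the log2 scale in EV and at -0.0247, -0.0243 and -0.0154 in VaWRKY12 (exact permutation p = 0.1, the smallest possible, adjusted p = 0.475 over 19 chromosomes). Chromosomes 1, 5 and 8 gave the same p. Chromosome 2 lay at -0.12 in EV replicate 2 and between -0.0231 and 0.0402 in the other libraries, and chromosome 15 lay at -0.0615 in EV replicate 1. Outside these 2 chromosomes the medians stayed within 0.0305 of 0.

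**Figure D4:**
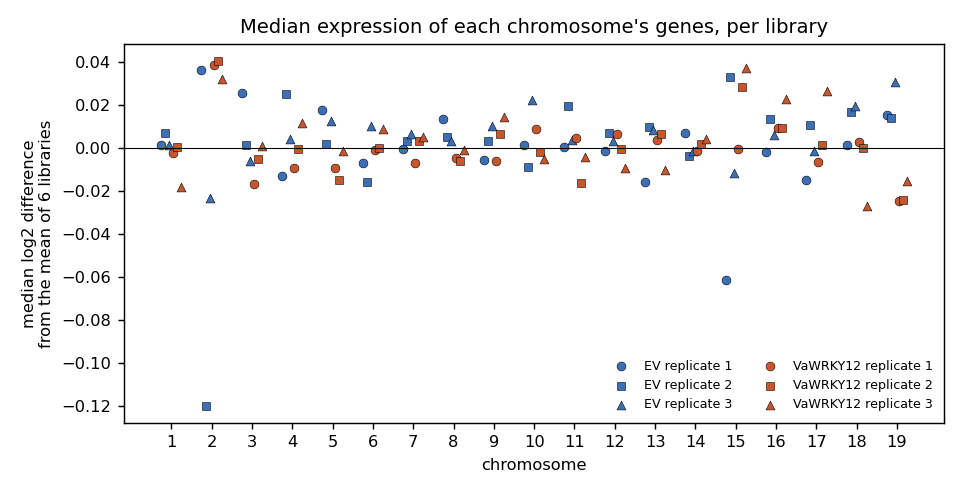
Median log2 difference of each chromosome's genes from the mean of the 6 libraries (vertical), by chromosome (horizontal), with 1 point per library. Chromosome 2 in EV replicate 2 (-0.12) and chromosome 15 in EV replicate 1 (-0.0615) lie farthest from 0.

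The authors' deposited table calls 944 genes higher and 981 lower at a false discovery rate under 0.05. Of these, 1865 were called in the same direction here, 60 were called only in the authors' deposited table, 80 only here and 0 in opposite directions. Across genes the log2 fold changes here and in the authors' deposited table correlated at 0.9996.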

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

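Counts of higher genes ran from 457 to 975 and of lower genes from 524 to 1005 when single libraries were left out, and the libraries that moved them most are given with the counts. With an absolute log2 fold change of at least 1 required, 460 and 419 genes were called, a smaller count by construction. With genes of whole reads only, an alternative added after seeing the data that tests fewer genes, 627 were higher and 589 lower. DESeq2 called 1189 and 1211, limma-voom 860 and 993, and library totals alone 1010 and 881. No gene called in the main test was called in the opposite direction under any alternative that was run. The correlation of deviations between same-numbered libraries was -0.063, 0.325 and 0.175 for replicates 1, 2 and 3, and only replicate 2 correlated best with its own number, so the numbers were not taken to pair the samples. With the replicate number as a block, 1123 genes were higher and 1129 lower. Of the named genes, GSVIVT01015895001 missed the adjusted p threshold without single libraries. It and GSVIVT01022705001 changed by less than 1 on the log2 scale, and neither was tested among whole-read genes. GSVIVT01035801001 and GSVIVT01021182001 passed in each alternative that tested them, which leaves out the filter at a mean of 50 counts. The ratio of same-direction neighbouring pairs to permuted order stayed between 1.60 and 3.08 over 17 alternatives, and the ratio of fallen to risen genes in the most abundant class between 1.74 and 3.69. Gene list tests and the level of WRKY12 were not run, since no descriptions were matched, and the alternatives for files without counts did not apply. Depth sets a floor for the low genes, where 3 reads stand for 0.2 to 0.341 CPM. Simulated changes of 1 on the log2 scale were recovered for 69.9% of genes drawn at all levels of expression. This share was not split by level, so it does not measure what depth costs the low genes. It also comes from sets with 200 changed genes, fewer than the 1945 called here.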

Other observations

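The tests of shared reads, of opposite-strand neighbours, of long segments, of windows along chromosome 2 and of the odds ratio after cyclic loess were chosen after the results were seen. The 6 libraries can be split into 3 and 3 in 10 ways. The real split called 940 higher and 1005 lower genes, and 1 of the 10 splits, the real one, gave as many in each direction. The highest count in the other splits was 0 by edgeR's quasi-likelihood test, with 122 to 961 genes at an unadjusted p under 0.05. Each other split mixes both genotypes in each group, so the difference between genotypes adds to the spread within groups and lowers the calls. The 0 is therefore no estimate of false calls. With 10 splits no share under 0.05 can be reached.

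Neighbouring genes changed alike, with a Spearman's rho of 0.110 (95% bootstrap interval 0.0924 to 0.127) between their log2 fold changes across 16284 pairs, which are not independent replicates. Neighbours with whole reads in all 6 libraries still gave 0.0834 (0.0597 to 0.107), which argues against reads split as fractions as the whole cause, and pairs 10 genes apart gave 0.00714 (-0.00824 to 0.0234), which argues against shifts of long segments. Whether 1 gene split into a pair of models accounts for part of it cannot be told apart: same-strand neighbours more than 10 kb apart gave 0.133 (0.0930 to 0.172), but 1093 genes have introns over 10 kb, so a higher same-strand value is also what split models predict and not, as first set, evidence against them. Opposite-strand neighbours, which cannot test it, gave 0.0381 (0.0152 to 0.0597), with 0.0549 (0.0196 to 0.0904) over 10 kb apart and 0.0251 (-0.00207 to 0.0536) within 10 kb, where same-strand neighbours gave 0.194 (0.165 to 0.222). Copies of a gene lying side by side, or control shared by a short stretch of a chromosome, may underlie the excess, as hypotheses that were not tested without gene names or sequences, and reads of near-identical copies counted whole also stay open.

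Genes of chromosome 2 were lower in EV replicate 2 than in the mean of the other 5 libraries, with a median of -0.144 on the log2 scale (95% bootstrap interval -0.161 to -0.114), or 9.47% lower. Of its 608 genes 69.2% lay below (65.4 to 72.9), against 42.8% to 52.6% on the other chromosomes, so the shift was spread over most of its genes. A few strongly changed genes could hardly move a median over 608 genes, so this share is not a separate test against them. The median was -0.145 (-0.163 to -0.117) after trends with level, coding length and exon number were removed. Of 13755 shifts of the gene order, 0 gave a median as far from the genome median, and the farthest lay 0.0423 away. The share, 7.3e-05, is the smallest they can give and lay under the bound of 0.00044 set for all chromosomes and libraries. Shifted stretches of genes overlap heavily, so this share is not a p-value at that resolution. A candidate explanation is that part of the cells of that library carried fewer copies of chromosome 2. The medians of 12 of 12 windows along chromosome 2 lay below 0, from -0.21 to -0.0629. With 69.2% of its genes below, this was likely in advance and cannot tell fewer copies from another shift of the whole chromosome. DNA was not measured, so fewer copies stay a hypothesis. The median log2 fold change of chromosome 2 between groups was 0.0823 with all libraries. It ran from 0.05 without EV replicate 2 or VaWRKY12 replicate 1 to 0.119 without EV replicate 1.

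Abundant genes fell more often than they rose, and a smooth trend of fold change with level could contribute. The balance of fallen and risen genes also shifted with level among the less abundant genes, which such a trend predicts. After cyclic loess scaling in limma-voom, 141 of the abundant genes were fallen and 73 risen, a ratio of 1.93, against 3.31 in limma-voom without it, that lay between the bounds set beforehand for and against such a trend. In that fit the odds ratio among called genes was 1.81 (95% interval 1.33 to 2.47, Fisher's exact test across genes, p = 7.97e-05). An excess of falls thus remained after this scaling. The interval treats genes as independent, though neighbouring calls clustered, and a trend that the scaling left in place stays open as the cause. Reads shared between gene models also stay open. Of all genes with fractions of reads, 436 fell and 317 rose, while 569 whole-read genes fell and 623 rose. In the fit to whole-read genes alone the ratio of fallen to risen in the most abundant class was 1.74. How much of the pattern the trend or shared reads carry, and whether VaWRKY12 overexpression carries the rest, cannot be told apart in these libraries.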
